A study of Homo sapiens with 9 samples.

How the data were processed

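The deposited intensity values were made by the authors with Affymetrix MAS5, per the submitters' processing notes. No source states a scaling, but the trimmed mean signal was 500.1 to 500.2 on every array. The MAS5 version is not given in the sources used here. The values came without detection calls.

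Each signal was turned into log2(signal + 25.1), where the pseudocount is the 20th percentile of all values. Of the 22283 probe sets, 68 are controls, 19065 name one gene, 1043 name several and 2107 name none, and only those with one gene were tested. Probe sets whose mean signal lay under the 30th percentile (53.3) were dropped, which left 13665, and each gene was represented by its probe set of highest mean, which gave 9100 genes. Signals are printed on the MAS5 scale with the standard deviation, and log2 fold changes with the standard error.

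Group means were fitted to all 9 arrays with limma 3.58.1 in R 4.3.3, with eBayes and its trend option, 4 residual degrees of freedom and 7.40 prior degrees of freedom. All tests were two-sided, with the Benjamini-Hochberg adjustment and a threshold of 0.05. The spread of the unnumbered EZH2 siRNA, with its single array, was taken from the groups of 2. An exact permutation test of 2 arrays against 2 cannot go below p = 0.333, so none was used. EZH2 was adjusted over its 6 comparisons alone, a choice made after its values had been seen.

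The arrays, the comparisons, the threshold, the filter, the pseudocount, the 21 gene lists and most of the alternatives were set before the data were examined. The lists hold 255 tested genes and share 0 genes. Those with at least 3 tested genes went through camera, with its preset correlation of 0.01 and with an estimated correlation. A study gene was not analysed here.

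Genes were named by a rule set before the data were examined. EZH2 was taken in every array. Each main comparison then gave up to 10 genes each way with non-overlapping groups, the largest changes among genes past the threshold, filled up by the smallest unadjusted limma p and reported as not past the threshold. The mean of both siRNAs and the difference of effects gave 5 each way. From each list came the members past the threshold or, where there were none, the 2 with the smallest p, and the study genes were given whatever their values.

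The fit and the list test were tested on simulated data with 200 changed genes among 9100, in 20 simulations. The changed genes were spread equally over 2-fold, 4-fold, 8-fold and 16-fold changes. With EZH2 siRNA no.2 the fit recovered 26.9% of genes changed 2-fold, 92.2% of those changed 4-fold and 99.6% of those changed 8-fold. With TSA the shares were 29.1%, 93.1% and 99.6%. Many large changes ease the Benjamini-Hochberg threshold for the other genes, so these shares overstate the recovery where few genes change strongly. Each simulation made 9.65 false calls on average. A list of 16 genes shifted by 0.5 was called in 19 of 20 simulations with EZH2 siRNA no.2, and 0 of the lists without a shift were called. The simulated genes varied independently of each other, so this does not show how often lists of correlated genes are called without a shift.

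The alternatives were pseudocounts at the 5th percentile (5.42) and the 40th percentile (87.2), no filter, a filter at the 50th percentile, every probe set, quantile normalization, each array scaled to the same median, eBayes without the trend, only the groups of a comparison, the 3 EZH2 siRNA arrays as one group, a replicate block and each array left out in turn. A batch block taken from the 18 hybridisation control probe sets, an adjustment of the fold changes for mean signal and genomic span (loess), and the gene families were added after the data had been seen. Matched random lists numbered 10000, and shared controls were simulated with 100 draws, with the overlap of genes and the draws of 1 array per siRNA added after the observed values had been seen.

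RNA quality probe sets gave 3' to 5' signal ratios of 1.03 to 1.44 for ACTB and 0.846 to 1.03 for GAPDH. The ACTB ratio was higher in TSA than in DMSO in replicate 1 (1.25 against 1.14) and in replicate 2 (1.44 against 1.29). The GAPDH ratio was lower in TSA in replicate 1 (0.846 against 0.997) and higher in replicate 2 (1.02 against 0.968). The first principal component held 24.2% of the variance and separated the replicate numbers.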

Results

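Gene expression was measured in A673 cells, a Ewing sarcoma cell line that carries the EWS/FLI fusion gene, on 9 human Affymetrix arrays. EZH2 is the histone methyltransferase of Polycomb repressive complex 2 (PRC2), and the study asked what it contributes to the growth and undifferentiated state of Ewing tumours. Cells were transfected with 5 nM siRNA for 48 hours, which gave 2 arrays for the control siRNA, 2 for EZH2 siRNA no.2 and 1 for another EZH2 siRNA whose title gives no number (the unnumbered EZH2 siRNA). The other 4 arrays came from cells held for 24 hours in 100 nM trichostatin A (TSA), an inhibitor of histone deacetylases, or in 0.01% DMSO, its solvent, with 2 arrays each.

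The median signal of an array ran from 125 to 159 and its highest signal from 27430.4 to 39131. The trimmed mean was 500.1 to 500.2 on every array. Arrays of the same group correlated across probe sets at r = 0.957 to 0.969. The hybridisation control probe sets split the arrays by replicate number, with mean log2 signals of 9.80 to 10.16 on 5 arrays (those of replicate 1 and the unnumbered EZH2 siRNA) and 10.43 to 10.53 on the 4 arrays of replicate 2. The number of arrays limits the precision. Their titles call the replicates biological, but nothing says whether they were separate cultures, so each p measures only the spread between these samples.

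EZH2 itself was measured first, since it checks the labels. Its mean signal fell from 1151 ± 29.9 (SD, n = 2) with the control siRNA to 421 ± 213 (n = 2) with EZH2 siRNA no.2, which is 36.6% of the control. The log2 fold change was −1.48 (SE 0.32, limma adjusted p = 0.00396 over the 6 comparisons of EZH2, and 0.862 over all genes). The replicate 1 array gave a signal of 572 and the replicate 2 array 270.6, so the log2 fold changes by replicate number were −0.95 and −2.02. Without EZH2 siRNA no.2 replicate 2 the log2 fold change was −0.98 (limma adjusted p = 0.0105). The single array with the unnumbered EZH2 siRNA had a signal of 681, or 59.2% of the control (log2 −0.74, SE 0.39, limma adjusted p = 0.130). Its adjusted p was 0.0379 to 0.162 over the other settings, and it passed only with a batch block (0.0379). EZH2 signals were 926 ± 91.0 in DMSO and 1156 ± 143 in TSA (n = 2 each). Neither TSA against DMSO (log2 0.31, limma adjusted p = 0.353) nor DMSO against the control siRNA (log2 −0.31, limma adjusted p = 0.353) passed.

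**Figure D1:**
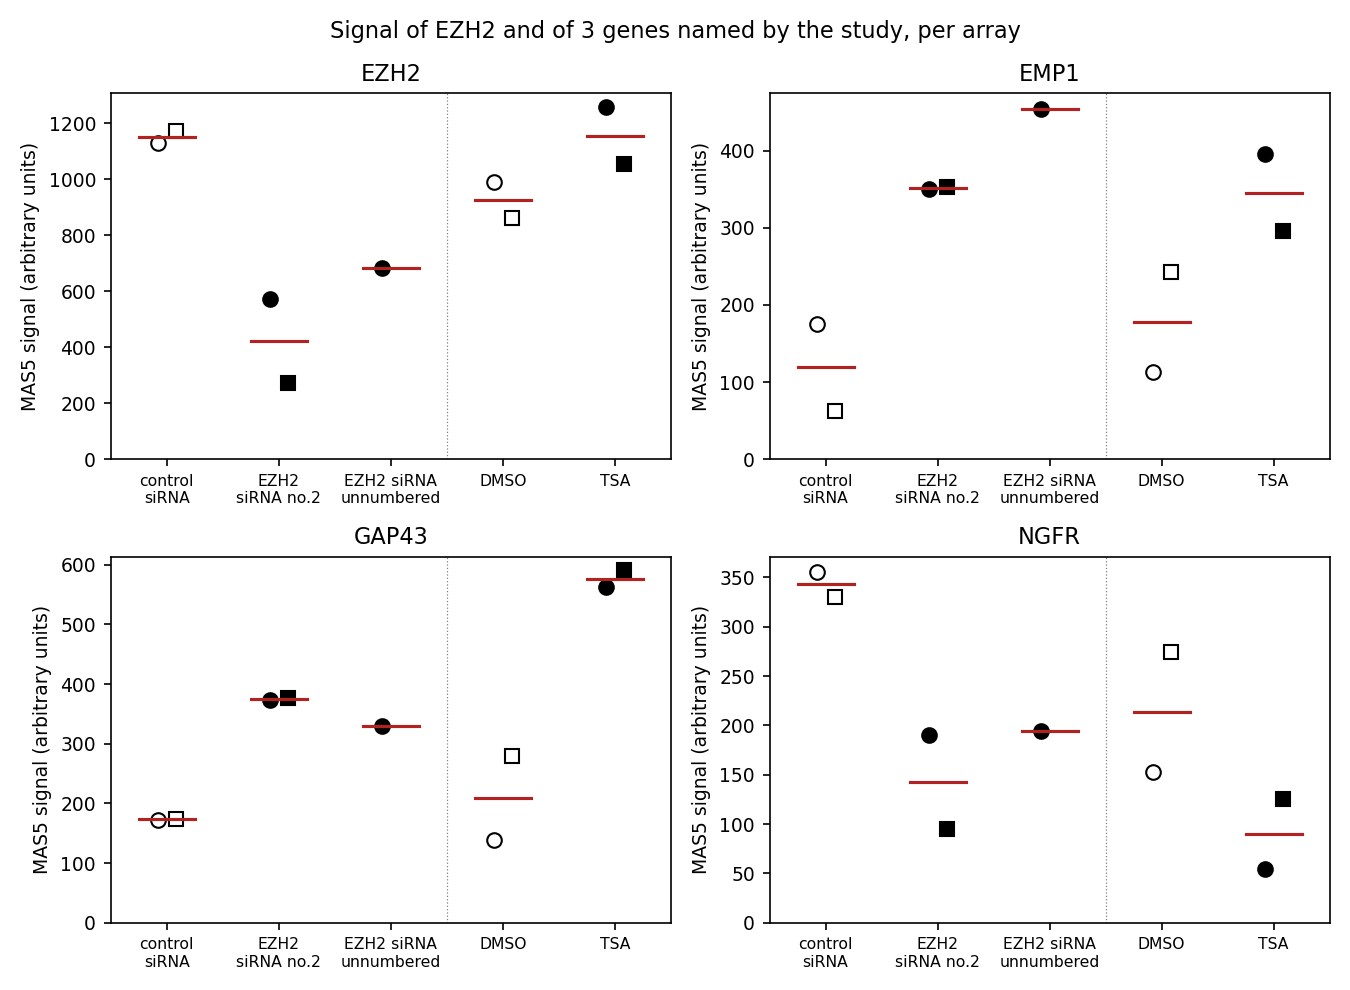
Signal (MAS5 units) of EZH2, EMP1, GAP43 and NGFR on each of the 9 arrays, with circles for replicate 1, squares for replicate 2, open symbols for the control siRNA and DMSO, and a red line at each group mean. EZH2 lies at 572 and 270.6 on the arrays with EZH2 siRNA no.2, below the control siRNA mean of 1151.

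Of the genes that the study itself followed, 3 were tested. EMP1, an epithelial membrane protein, had a signal of 119 ± 79.6 with the control siRNA and 352 ± 1.49 with EZH2 siRNA no.2 (n = 2 each, log2 1.51, SE 0.42). GAP43, a growth cone protein, went from 174 ± 1.46 to 375 ± 3.11 (log2 1.01, SE 0.31), and NGFR, the low-affinity neurotrophin receptor, from 343 ± 18.1 to 143 ± 67.1 (log2 −1.19, SE 0.41). In TSA, GAP43 had a signal of 576 ± 20.2 against 209 ± 99.5 in DMSO (log2 1.43, SE 0.31). EMP1 stood at 345 ± 70.3 against 178 ± 91.8 (log2 0.93, SE 0.42) and NGFR at 89.9 ± 49.6 against 213 ± 85.9 (log2 −1.07, SE 0.41).

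All 3 study genes tested passed limma with EZH2 siRNA no.2 when adjusted over the list alone (adjusted p = 0.0117 for EMP1, 0.0117 for GAP43 and 0.0137 for NGFR). All 3 also passed with TSA when adjusted over the list alone (adjusted p = 0.00221 for GAP43, 0.0347 for NGFR and 0.0477 for EMP1). The study chose these genes, so these counts are not independent evidence, and over all genes the adjusted p was 0.862 for the siRNA and 1.00 for TSA. With the siRNA, EMP1 gave 0.91 without control siRNA replicate 2 and NGFR −0.77 without EZH2 siRNA no.2 replicate 2. With TSA, EMP1 gave 0.45 without DMSO replicate 1 and 1.41 without DMSO replicate 2, and NGFR gave −0.70 without DMSO replicate 2 and −0.62 without TSA replicate 1. The other GAP43 probe sets read 0.02 and 0.93 with the siRNA and 0.63 and 1.36 with TSA. Of the other EMP1 probe sets, one read 0.90 and 0.50, and one below the filter had signals of 21.3 ± 0.496 with the control siRNA, 42.3 ± 4.15 with EZH2 siRNA no.2, 38.2 ± 7.31 in DMSO and 40.6 ± 6.88 in TSA. GFAP, an astrocyte filament gene, lay below the filter, with signals on its brighter probe set of 14.6 ± 6.85 with the control siRNA, 50.9 ± 23.2 with EZH2 siRNA no.2, 67.3 with the unnumbered EZH2 siRNA, 20.8 ± 4.32 in DMSO and 66.8 ± 9.25 in TSA. Its other probe set had group means of at most 10.6. As a list, these genes did not pass camera with EZH2 siRNA no.2 (adjusted p = 0.546) or with TSA (adjusted p = 0.246). With TSA the list passed with no filter (0.0375), with every probe set (0.00135) and without DMSO replicate 2 (0.0426).

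EZH2 siRNA no.2 was set against the control siRNA to ask which genes follow EZH2. ERBB4, a receptor tyrosine kinase, had a signal of 446 ± 1.27 with the EZH2 siRNA against 170 ± 10.0 with the control siRNA (log2 1.27, SE 0.28, n = 2 each here and below). NFE2L1, a transcription factor for proteasome genes, stood at 2535 ± 250.3 against 1236 ± 123 (log2 1.02, SE 0.23), and TNFRSF21, a death receptor, at 1565 ± 18.8 against 756 ± 121 (log2 1.03, SE 0.26). On the lower side were PPP1R1A, an inhibitor of protein phosphatase 1 and a known target of the fusion, at 910.2 ± 189 against 2836.5 ± 526 (log2 −1.62, SE 0.30), and DYNC1LI2, a dynein chain, at 409.9 ± 77.8 against 1208 ± 303 (log2 −1.49, SE 0.27). RBX1, the ring-finger subunit of cullin ligases, stood at 1564 ± 489 against 4370.3 ± 415 (log2 −1.50, SE 0.31). DMSO, without an EZH2 siRNA, was also above the control siRNA for ERBB4 (log2 1.42) and NFE2L1 (0.52). The ERBB4 difference was thus not particular to the EZH2 siRNA, and low control siRNA arrays may carry it. The same comparison gave −0.0095 for TNFRSF21, −0.15 for PPP1R1A, −0.26 for RBX1 and −0.52 for DYNC1LI2.

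Other genes were taken by the smallest limma p among those with non-overlapping groups. IL7R had a signal of 119 ± 65.9 against 15.9 ± 10.5 (log2 1.75, SE 0.45), NRP1, a semaphorin coreceptor, 244 ± 0.921 against 96.1 ± 34.7 (log2 1.18, SE 0.31), and MARCKS, a protein kinase C substrate, 1988 ± 314 against 858 ± 358 (log2 1.24, SE 0.32). The log2 fold changes were 1.43 (SE 0.36) for CLIP1, 1.31 (SE 0.32) for the metal ion transporter SLC11A1, 1.07 (SE 0.28) for PEX14 and 1.05 (SE 0.27) for the cystine transporter SLC7A11. Lower genes included the neuropeptide GRP, with 5212 ± 381 against 10053 ± 1974 (log2 −0.93, SE 0.22), the neural proteoglycan CSPG5 (log2 −1.02, SE 0.25), the elongation factor SUPT4H1 (log2 −1.03, SE 0.26), and the complex I subunits NDUFA1 (log2 −1.53, SE 0.38) and NDUFS7 (log2 −0.99, SE 0.25). TMEM50A gave −1.69 (SE 0.38), with −0.76 and −2.62 by replicate number, but −0.05 with the unnumbered EZH2 siRNA. Other probe sets of some of these genes differed less, with log2 fold changes of 0.24 for ERBB4, 0.20 for PEX14, 0.72 for CLIP1, 0.46 for NRP1, 0.57 and 0.50 for SLC7A11, 0.85 and −0.12 for SLC11A1, −0.37 for DYNC1LI2, −0.23 for CSPG5 and −0.38 for SUPT4H1. MARCKS gave 0.82 without control siRNA replicate 2. DMSO against the control siRNA also gave 1.61 for IL7R, 1.17 for CLIP1, 0.84 for MARCKS and 0.52 for NRP1. Low control siRNA arrays may therefore carry part of these changes. It gave 0.36 for SLC11A1, 0.22 for SLC7A11, 0.06 for PEX14, and −0.46 to −0.13 for the lower genes named here. The IL7R control signal lay below the pseudocount of 25.1, and its log2 fold change ran from 0.96 to 2.52 over the other settings.

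Of the 9100 genes tested with EZH2 siRNA no.2, 0 passed limma at an adjusted p under 0.05, and the lowest adjusted p was 0.862 (0.418 to 0.920 over the other settings). At an unadjusted limma p under 0.05 there were 520 genes, 5.71% of those tested, where chance alone gives 455, with 360 higher and 160 lower. The other settings gave 403 to 807 genes, among them 807 with a batch block, and 0 past the adjusted threshold in every case. The direction of this split depended on the scaling, with 267 higher and 206 lower after quantile normalization. It was 179 higher and 337 lower with each array scaled to the same median, which moved the median log2 fold change of all genes from 0.08 to −0.06. Changes of at least 2-fold without overlap between groups were seen for 127 genes upward and 39 downward, and 33.3% of unchanged genes show no overlap by chance with 2 arrays against 2.

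The 21 gene lists were fixed before the data were examined, and 20 had enough genes for a list test. Genes that EWS/FLI represses stood higher with EZH2 siRNA no.2, where 13 of 16 were positive and the mean log2 fold change was 0.53 ± 0.11 (SEM, n = 16 genes). CCN1 (1.17, SE 0.32) and COL5A2 (1.14, SE 0.32) passed limma adjusted over the list alone (adjusted p = 0.0339 each). CCN2 (1.13, SE 0.39), CD44 (0.82, SE 0.43), IGFBP3 (0.80, SE 0.50), TNC (0.72, SE 0.30) and LOX (0.66, SE 0.39) were also higher. TIMP3 was lower (−0.36, SE 0.33). Values did not overlap between groups for 11 members, all higher. The list passed camera (adjusted p = 0.000466, and adjusted p = 0.847 with an estimated correlation). Its mean was 0.24 in replicate 1 and 0.81 in replicate 2, and without EZH2 siRNA no.2 replicate 2 the mean was 0.34 and the call was lost (adjusted p = 0.169).

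Genes that EWS/FLI activates stood lower, with 14 of 21 negative and a mean log2 fold change of −0.23 ± 0.12 (SEM, n = 21 genes). PPP1R1A fell when adjusted over the list alone (limma adjusted p = 0.00445). NKX2-2 (−0.97, SE 0.42), GSTM4 (−0.71, SE 0.23), FCGRT (−0.60, SE 0.29), JAK1 (−0.60, SE 0.26) and ID2 (−0.59, SE 0.25) were lower. DKK2 was higher (0.91, SE 0.32). Without overlap between groups, 6 members were lower and 3 higher, where 33.3% of unchanged genes show no overlap by chance. The list passed camera (adjusted p = 0.00263, and adjusted p = 0.847 with an estimated correlation). The call was lost after quantile normalization (−0.21, adjusted p = 0.0842) and without EZH2 siRNA no.2 replicate 2 (−0.09, adjusted p = 0.517). The mean was −0.04 in replicate 1 and −0.42 in replicate 2, −0.37 without EZH2 siRNA no.2 replicate 1, −0.37 with each array scaled to the same median and −0.15 with no filter.

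**Figure D2:**
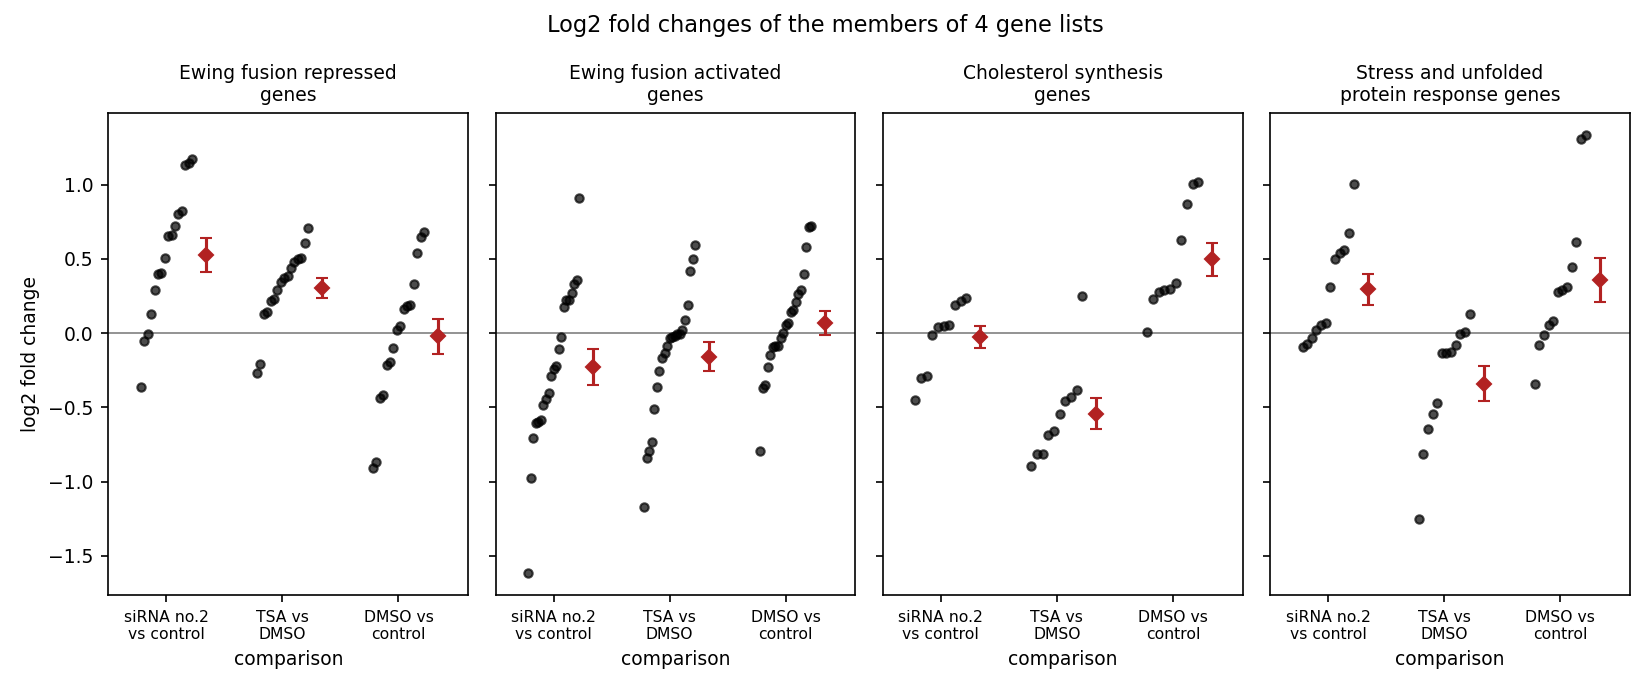
Log2 fold change of each gene (black points) in 4 lists for EZH2 siRNA no.2 against control siRNA, TSA against DMSO, and DMSO against control siRNA, with the mean as a red diamond and its SEM as a bar. The cholesterol synthesis list lies at −0.54 in TSA against DMSO and at 0.50 in DMSO against control siRNA, and the list repressed by the fusion at 0.53 with EZH2 siRNA no.2.

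The remaining lists did not pass with EZH2 siRNA no.2. Neuronal genes had 17 of 26 positive and a mean of 0.12, with NEFH at 1.04 (SE 0.48) and NEFM at 0.71 (SE 0.47), while camera placed the list below the other genes (adjusted p = 0.980). The 20 Polycomb target genes had a mean of 0.03 with 11 positive, including HOXB6 (0.70, SE 0.44) and HOXD11 (0.58, SE 0.26), and camera again pointed down (adjusted p = 0.828). PRC2 and PRC1 genes other than the siRNA's target included JARID2 (0.74, SE 0.26) and PHC2 (0.65, SE 0.26). The whole list of 17, which includes EZH2 itself at −1.48, had a mean of −0.04 and a median of 0.02 (camera adjusted p = 0.768). Of the 29 cell cycle genes 19 were negative (mean −0.10, adjusted p = 0.0782), with CCNE2 at −0.62 (SE 0.31) and CDK1 at −0.38 (SE 0.25), and this list passed with each array scaled to the same median (−0.24, adjusted p = 0.0422). It also passed without control siRNA replicate 2 (−0.20, adjusted p = 0.00103) and without EZH2 siRNA no.2 replicate 1 (−0.22, adjusted p = 0.000375). Among the 7 stem cell genes, TERT was at −1.14 (SE 0.34, limma adjusted p = 0.0402 adjusted over the list alone) and NES at 1.41 (SE 0.51), and the mean was 0.02 while camera pointed down (adjusted p = 0.828). The p53 and apoptosis list had a mean of 0.09 (adjusted p = 0.828), with BCL2L1 at 1.24 (SE 0.44), CASP8 at 0.83 (SE 0.29) and BAX at −0.99 (SE 0.41), and 0 members passed limma adjusted over the list alone.

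Stress genes had a mean of 0.29 with 9 of 12 positive (adjusted p = 0.245), led by TRIB3 (1.00, SE 0.37) and HSPA5 (0.68, SE 0.27). The stress list passed without control siRNA replicate 1 (0.52, adjusted p = 0.00162) and after an adjustment for mean signal and genomic span (0.31, adjusted p = 0.0155). The list means were 0.24 for fibroblast genes (adjusted p = 0.767, COL3A1 0.87, SE 0.41) and 0.16 for endothelial genes with 7 of 8 positive (adjusted p = 0.768). They were 0.14 for hypoxia genes (adjusted p = 0.768) and 0.10 for histone deacetylases (adjusted p = 0.828). Interferon genes had a mean of −0.09 (adjusted p = 0.253, ISG15 −0.68, SE 0.31), and genes known to answer deacetylase inhibitors −0.08 (adjusted p = 0.767). The latter list passed without control siRNA replicate 2 (−0.36, adjusted p = 0.00309). Cholesterol synthesis genes had a mean of −0.03 with 6 of 10 positive and a median of 0.04 (adjusted p = 0.768), and housekeeping genes −0.04 (adjusted p = 0.767). Epithelial genes had a mean of 0.10 (adjusted p = 0.828) and blood genes 0.31 (adjusted p = 0.768), with 3 genes each. Of the 9 cancer-germline genes on the array only 2 passed the filters and were tested, MAGEA12 (0.70, SE 0.39) and SSX1 (−0.36, SE 0.26). With each array scaled to the same median, the means of the Polycomb target (−0.10), stem cell (−0.11), p53 (−0.05), histone deacetylase (−0.04), epithelial (−0.03) and neuronal (−0.01) lists turned negative, and after quantile normalization the housekeeping mean was 0.04.

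TSA was set against DMSO to ask which genes follow the inhibition of histone deacetylases. SULT1E1, an estrogen sulfotransferase, had a signal of 528 ± 239.5 in TSA against 111 ± 30.5 in DMSO (log2 1.97, SE 0.48, n = 2 each here and below). KCNJ5, a potassium channel, was higher (log2 1.27, SE 0.31), and SOX11, a neural transcription factor, stood at 1015 ± 289 against 517 ± 161 (log2 0.94, SE 0.30). PCYT2, an enzyme of phospholipid synthesis, was lower, at 409 ± 9.81 against 943 ± 167 (log2 −1.15, SE 0.25), as was CHAC1, a target of the amino acid response, at 109 ± 41.2 against 315 ± 41.1 (log2 −1.37, SE 0.35). PPP1R1A stood at 1140.3 ± 359 against 2574 ± 641 (log2 −1.17, SE 0.30). In DMSO against the control siRNA, KCNJ5 was lower (−0.73), and PCYT2 (0.71) and CHAC1 (0.85) were higher. The DMSO arrays may therefore carry part of these 3 changes. The same comparison gave 0.44 for SULT1E1, −0.04 for SOX11 and −0.15 for PPP1R1A.

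Several of the other higher genes had low signals in DMSO, such as HTR1E with 68.1 ± 12.1 against 11.2 ± 3.72 (log2 1.36, SE 0.38), PCOTH with 95.0 ± 8.85 against 22.2 ± 3.73 (log2 1.34, SE 0.35), and CPA3 with 82.6 ± 22.7 against 14.8 ± 6.06 (log2 1.43, SE 0.41). AMBN gave 1.91 (SE 0.54), with 2.82 and 1.00 by replicate number, and SULT1E1 2.66 and 1.28. PRKCE (1.19, SE 0.38) and PARG (0.88, SE 0.26) were also higher. Over the other settings HTR1E ran from 0.66 to 2.15, PCOTH from 0.73 to 1.86, CPA3 from 0.73 to 2.13 and PRKCE from 0.71 to 1.54. Lower genes included SAYSD1 (−1.50, SE 0.32), the steroid receptor PAQR5 (−1.42, SE 0.33), FAM162A (−1.17, SE 0.28), QDPR (−1.16, SE 0.30), the thioesterase ACOT13 (−1.07, SE 0.27), HEBP1 (−1.04, SE 0.26) and the sterol synthesis scaffold ERG28, with 1483 ± 163 against 3006 ± 716 (log2 −0.99, SE 0.25). SAYSD1 ran from −1.91 to −0.92 over the other settings, and PAQR5 from −1.72 to −0.92. Other probe sets read 0.11 and −0.16 for KCNJ5, 0.23 and 0.38 for SOX11, and −0.07 for FAM162A, which gave −0.77 without TSA replicate 1. In DMSO against the control siRNA, CPA3 (−1.47), PCOTH (−1.11), HTR1E (−0.69), PRKCE (−0.61) and PARG (−0.28) were lower. ACOT13 (0.80), QDPR (0.57), FAM162A (0.45), PAQR5 (0.38) and ERG28 (0.23) were higher. The DMSO arrays may therefore carry part of the TSA changes of these genes. The same comparison gave 0.74 for AMBN, 0.05 for SAYSD1 and 0.0015 for HEBP1.

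With TSA 0 of the 9100 genes passed limma at an adjusted p under 0.05, and the lowest adjusted p was 1.00 (0.751 to 1.00 over the other settings). At an unadjusted limma p under 0.05 there were 238 genes (2.62%), fewer than the 455 that chance alone gives, with 116 higher and 122 lower. The other settings gave 182 to 414 genes, and 0 passed the adjusted threshold. The unadjusted count was 759 without TSA replicate 2 and 106 without DMSO replicate 1. The split was 105 higher and 143 lower after quantile normalization, and 66 higher and 161 lower with each array scaled to the same median. Changes of at least 2-fold without overlap were seen for 35 genes upward and 31 downward, with 33.3% of unchanged genes free of overlap by chance.

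Cholesterol synthesis genes were the clearest list in TSA, with 9 of 10 negative and a mean log2 fold change of −0.54 ± 0.10 (SEM, n = 10 genes). INSIG1 (−0.89, SE 0.26), IDI1 (−0.82, SE 0.28), FDPS (−0.81, SE 0.32), MVD (−0.69, SE 0.34) and SC5D (−0.66, SE 0.26) were lower, and SREBF2 was higher (0.25, SE 0.39). Values did not overlap for 9 members, and 0 passed limma adjusted over the list alone. The list passed camera (adjusted p = 2.72e-08, and adjusted p = 0.168 with an estimated correlation), with means of −0.51 in replicate 1 and −0.58 in replicate 2. The same genes stood higher in DMSO than with the control siRNA, and their mean in TSA against the control siRNA was −0.05 ± 0.12.

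Stress genes had a mean of −0.34 ± 0.12 and a median of −0.13 in TSA, with 10 of 12 negative (SEM, n = 12 genes). ASNS (−1.25, SE 0.36), HMOX1 (−0.81, SE 0.60), HERPUD1 (−0.65, SE 0.34), TRIB3 (−0.55, SE 0.37) and ATF4 (−0.47, SE 0.26) were lower. Groups did not overlap for 4 of the 12 members, no more than the chance share of 33.3%. The list passed camera (adjusted p = 0.00862, and adjusted p = 0.755 with an estimated correlation). The call was lost without DMSO replicate 2 (−0.26, adjusted p = 0.136) and without TSA replicate 1 (−0.15, adjusted p = 0.644). It was also lost after an adjustment for mean signal and genomic span (−0.28, adjusted p = 0.108). The mean was −0.53 without TSA replicate 2.

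Genes that EWS/FLI represses stood higher in TSA, with 14 of 16 positive and a mean of 0.30 ± 0.07 (SEM, n = 16 genes). CD44 (0.71, SE 0.43), TNC (0.61, SE 0.30), CCN2 (0.51, SE 0.39), COL5A2 (0.50, SE 0.32) and FN1 (0.48, SE 0.21) were higher. Without overlap between groups, 8 members were higher and 1 lower. The list passed camera (adjusted p = 0.00862, and adjusted p = 0.755 with an estimated correlation), with means of 0.46 in replicate 1 and 0.15 in replicate 2. The call was lost without DMSO replicate 1 (0.20, adjusted p = 0.187) and without TSA replicate 1 (0.25, adjusted p = 0.235).

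The genes known to answer deacetylase inhibitors did not pass in TSA as a list, with 13 of 19 positive and a mean of 0.07 (adjusted p = 0.764), including H2AC6 (0.63, SE 0.42), CDKN1A (0.46, SE 0.28) and H2BC12 (0.46, SE 0.34). The histone deacetylases themselves had 8 of 9 positive and a mean of 0.16 (adjusted p = 0.574). Genes that EWS/FLI activates had 15 of 21 negative and a mean of −0.16 (adjusted p = 0.0985), among them FCGRT (−0.73, SE 0.29). Neuronal genes had a mean of 0.10 (adjusted p = 0.840), with UCHL1 at −0.81 (SE 0.38) and ENO2 at −0.49 (SE 0.25). Polycomb target genes had a mean of 0.02 (adjusted p = 0.998), with HOXC10 at −0.62 (SE 0.24) and PAX6 at −0.64 (SE 0.36). The PRC2 and PRC1 genes had a mean of 0.08 (adjusted p = 0.574), with PHC1 at 0.57 (SE 0.25).

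Hypoxia genes had a mean of 0.14 in TSA (adjusted p = 0.713), with ADM at 0.66 (SE 0.30) and PFKFB3 at 0.63 (SE 0.31). In the p53 list, with a mean of 0.04 and a median of −0.05 (adjusted p = 0.962), GADD45A was at −0.70 (SE 0.27) and BCL2L11 at 0.92 (SE 0.49). Interferon genes had a mean of −0.06 but a median of 0.02 and 8 of 13 positive (adjusted p = 0.574), with ISG15 at −0.63 (SE 0.31). The stem cell list, with PROM1 at 0.93 (SE 0.34), had a mean of 0.05 and a median of −0.13 (adjusted p = 0.934). The means were 0.05 for fibroblast genes (adjusted p = 0.962), 0.03 for endothelial genes (adjusted p = 0.934) and 0.03 for cell cycle genes (adjusted p = 0.920). They were −0.02 for housekeeping genes (adjusted p = 0.840), −0.11 for blood genes (adjusted p = 0.766) and −0.17 for epithelial genes (adjusted p = 0.574). With each array scaled to the same median the Polycomb target (−0.05), cell cycle (−0.04), endothelial (−0.04), p53 (−0.03), fibroblast (−0.02) and stem cell (−0.02) means turned negative, and after quantile normalization the housekeeping mean was 0.08.

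The unnumbered EZH2 siRNA, on 1 array, was set against the control siRNA to ask whether another siRNA to EZH2 moves the same genes. EMP1 had a signal of 454 (log2 1.85, SE 0.51, limma adjusted p = 0.0116 adjusted over the list alone), GAP43 329 (log2 0.83, adjusted p = 0.0773) and NGFR 194 (log2 −0.74, adjusted p = 0.165). TERT gave −2.22 (SE 0.41, limma adjusted p = 0.00141 adjusted over its list alone) and BAX −1.55 (SE 0.51), while the neurofilaments NEFM (1.85, SE 0.57) and NEFH (1.75, SE 0.59) were higher. With a single array these p values take their spread from the other groups and do not cover the variation between samples of this siRNA. At an unadjusted limma p under 0.05 there were 467 genes, where chance alone gives 455. Of these 264 were higher and 203 lower (223 and 240 after quantile normalization, 160 and 298 with each array scaled to the same median). Under every setting 0 passed the adjusted threshold, and the lowest adjusted p was 0.370 (0.208 to 0.784 over the other settings). With all arrays kept no list passed, with the list repressed by the fusion at 0.31 ± 0.09 and 14 of 16 positive (adjusted p = 0.338). Stress genes stood at 0.30 and interferon genes at −0.17 (adjusted p = 0.338 each). Neuronal genes stood at 0.31, with 18 of 26 positive, and histone deacetylases at 0.27 (adjusted p = 0.357 each). Without control siRNA replicate 1 the stress list (0.52, adjusted p = 0.0124) and the list repressed by the fusion (0.41, adjusted p = 0.0470) passed.

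Over the mean of both EZH2 siRNAs, on 3 arrays against 2, EZH2 fell (log2 −1.11, SE 0.30, limma adjusted p = 0.00656). EMP1 had a signal of 386 ± 59.3 (n = 3) against 119 (log2 1.68, SE 0.39) and rose when adjusted over the list alone (limma adjusted p = 0.00355), as did GAP43 (log2 0.92, adjusted p = 0.0134), while NGFR fell (log2 −0.97, adjusted p = 0.0274). EMP1 gave 1.08 without control siRNA replicate 2. DGKZ, a diacylglycerol kinase, stood at 3208 ± 1826 against 1323 ± 258 (log2 1.35, SE 0.24, with 0.71 for no.2 and 2.00 for the unnumbered siRNA). MARCKS (1.32, SE 0.30), G3BP2 (1.39, SE 0.30), UBP1 (1.02, SE 0.23) and NFE2L1 (1.02, SE 0.22) were higher. G3BP2 gave 0.84 without control siRNA replicate 2, and its other probe sets read 0.35 and 0.26 with EZH2 siRNA no.2 and 0.28 and 0.55 with the unnumbered siRNA. DMSO against the control siRNA gave 0.90 for G3BP2, 0.84 for MARCKS, 0.52 for NFE2L1, 0.51 for UBP1 and 0.23 for DGKZ. TERT, at 73.9 ± 46.0 against 238 ± 60.3 (log2 −1.68, SE 0.32), fell when adjusted over its list alone (limma adjusted p = 0.0015), as did PPP1R1A (log2 −1.37, SE 0.28, adjusted p = 0.0098). DKK2 rose in the same list (log2 1.08, SE 0.30, adjusted p = 0.0383). DYNC1LI2 (−1.14, SE 0.25), NDUFB8 (−1.07, SE 0.24) and TBCB (−1.05, SE 0.24) were lower. The other NDUFB8 probe sets read −0.31 and 0.15 with EZH2 siRNA no.2 and −0.17 and 0.09 with the unnumbered siRNA.

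Of all genes 0 passed limma for the mean of both EZH2 siRNAs (lowest adjusted p = 0.654, with 0.277 to 0.7003 over the other settings), and 666 had an unadjusted p under 0.05, 441 higher and 225 lower. This split was 345 and 280 after quantile normalization, and 220 and 429 with each array scaled to the same median. The other settings gave 522 to 994 genes and 0 past the adjusted threshold. Genes repressed by the fusion had 13 of 16 positive and a mean of 0.42 ± 0.09 (camera adjusted p = 0.0123, and adjusted p = 0.817 with an estimated correlation). COL5A2 (1.10, SE 0.30), CCN1 (0.98, SE 0.30) and ANXA1 (0.66, SE 0.23) were higher. Groups did not overlap for 7 members, where 20% is the chance share. This call was lost with no filter (0.39), without control siRNA replicate 2 (0.32, adjusted p = 0.289) and without EZH2 siRNA no.2 replicate 2 (0.32, adjusted p = 0.138). Genes activated by the fusion (−0.11, adjusted p = 0.191), interferon genes (−0.13, adjusted p = 0.191) and stress genes (0.30, adjusted p = 0.208) did not pass in the chosen settings. With all arrays kept, interferon genes passed with the 50th percentile filter (−0.33, adjusted p = 0.0287) and with every probe set (−0.17, adjusted p = 0.0463). Genes activated by the fusion passed with every probe set (−0.14, adjusted p = 0.0256), and stress genes after the adjustment for mean signal and genomic span (0.32, adjusted p = 0.0152). Stress genes also passed without control siRNA replicate 1 (0.52, adjusted p = 0.00159), interferon genes without the same array (−0.36, adjusted p = 0.0460), and genes activated by the fusion without EZH2 siRNA no.2 replicate 1 (−0.18, adjusted p = 0.0117). Without control siRNA replicate 2 cell cycle genes (−0.13, adjusted p = 0.0196) and genes known to answer deacetylase inhibitors (−0.29, adjusted p = 0.0182) passed.

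The siRNA and TSA comparisons were set side by side to ask whether lowering EZH2 and inhibiting deacetylases move the same genes. SOX11 (0.83 with EZH2 siRNA no.2 and 0.94 with TSA), JUN (0.83 and 0.88), ARC (1.01 and 0.98), HMGA2 (0.72 and 0.74) and TGFBI (0.73 and 0.55) were higher with both. IFITM3 (−0.63 and −0.73), VEGFB (−0.64 and −0.74), RBX1 (−1.50 and −0.71) and GSTM4 (−0.71 and −0.51) were lower with both. Each SE was 0.39 or less. At unadjusted p under 0.05, 21 genes were higher with both where independent lists of these sizes share 4.59, and 25 were lower with both where 2.15 are shared. Arrays simulated without any effect shared 9.29 higher genes on average and at most 18, and 9.34 lower genes and at most 20. OCEL1, OPRK1 and HIPK1 had opposite signs, although the other HIPK1 probe set read −0.49 with the siRNA and −0.18 with TSA. Across the 9100 genes, which are not independent replicates, the fold changes correlated at r = 0.255 (Spearman's rho 0.260) and 60.8% had the same sign, although the comparisons share no array. By replicate number r was 0.361 and 0.128, and it was 0.111 without DMSO replicate 1, 0.154 without control siRNA replicate 1 and 0.158 without EZH2 siRNA no.2 replicate 1.

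The EZH2 siRNAs shared 103 higher genes, including EMP1, MARCKS, NRP1, ITGB1 and COL5A2, and 48 lower genes, including TERT, BAX, RET, CDK5 and GRP. Both use the same control arrays, and arrays simulated without any effect shared 36 higher genes on average and at most 53, and 37.3 lower genes and at most 54, so the lower count lay within the simulated range. The simulated counts were alike both ways, but the observed lists held 360 and 264 higher genes and 160 and 203 lower ones. Their lengths depended on the scaling, so the higher and lower counts cannot be set against each other. The simulated lists were not matched to these lengths, so the simulated range does not decide whether the lower count exceeds chance. Independent lists of these sizes share 10.4 and 3.57. Their fold changes correlated at r = 0.595 (rho 0.599) with the same sign for 72.8% of genes. Unchanged groups simulated against the same control arrays gave a mean r of 0.408 and at most 0.431. Without EZH2 siRNA no.2 replicate 1, which had low hybridisation controls like the array of the unnumbered siRNA, r was 0.416, where simulated unchanged groups with 1 array per siRNA gave a mean of 0.331 and at most 0.357. The covariance was 0.104 against a simulated 0.0604, a difference of 0.0436. The control arrays were too few to split, so part of the excess may come from them. Differences between arrays can also raise r, since splits by replicate number of arrays that were not shared correlated at 0.333. The simulated highest values are therefore no firm limit, and the excess does not show a shared effect of the siRNAs. The unnumbered EZH2 siRNA and TSA, which share no array, correlated at r = 0.256 (rho 0.270).

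**Figure D3:**
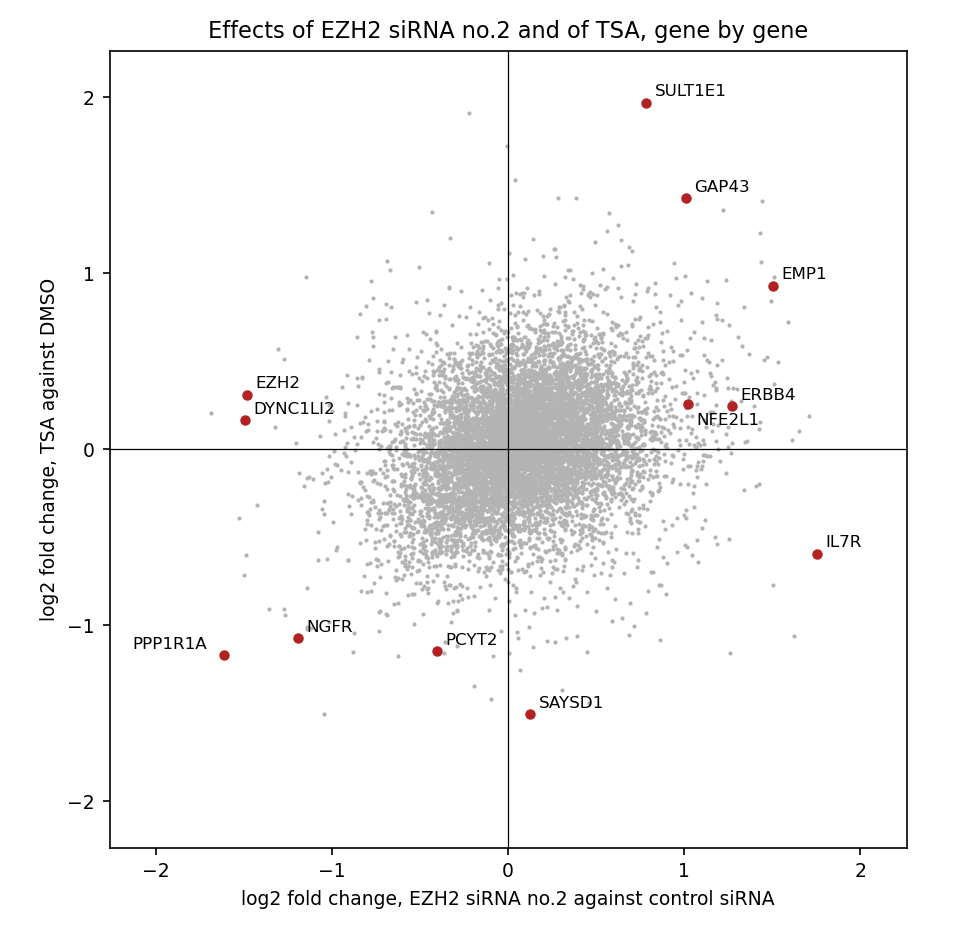
Log2 fold change with EZH2 siRNA no.2 against control siRNA (x axis) and with TSA against DMSO (y axis) for 9100 genes (grey points), with 12 named genes in red. The fold changes correlate weakly (r = 0.255), with GAP43 and EMP1 higher and PPP1R1A and NGFR lower in both.

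The TSA effect was also tested directly against the EZH2 siRNA no.2 effect, as their difference. Stress genes had 12 of 12 negative and a mean difference of −0.63 ± 0.16 (SEM, n = 12 genes), with TRIB3 at −1.55 (SE 0.52), ASNS at −1.32 (SE 0.51), HERPUD1 at −1.19 (SE 0.49) and HMOX1 at −1.12 (SE 0.85). Cholesterol synthesis genes had 9 of 10 negative and a mean difference of −0.52 ± 0.12 (SEM, n = 10 genes), with INSIG1 at −1.11 (SE 0.37), FDPS at −0.86 (SE 0.45), MVD at −0.74 (SE 0.49) and HMGCS1 at −0.67 (SE 0.38). Both lists passed camera, with adjusted p = 0.000352 for stress and 0.000369 for cholesterol synthesis, and with an estimated correlation adjusted p = 0.828 and 0.602. The stress call was lost without control siRNA replicate 2 (−0.41, adjusted p = 0.160) and without TSA replicate 1 (−0.45, adjusted p = 0.0612), and the cholesterol call without TSA replicate 2 (−0.38, adjusted p = 0.131). The list repressed by the fusion differed by −0.22 (adjusted p = 0.377), the deacetylase inhibitor list by 0.15 (adjusted p = 0.377) and cell cycle genes by 0.13 (adjusted p = 0.0761). Without control siRNA replicate 2 the deacetylase inhibitor list (0.43) and cell cycle genes (0.23) passed (adjusted p = 0.000487 each). Cell cycle genes also passed without EZH2 siRNA no.2 replicate 1 (0.25, adjusted p = 0.00162) and without DMSO replicate 1 (0.17, adjusted p = 0.0273). The list repressed by the fusion (−0.41, adjusted p = 0.0403) and that activated by it (0.21, adjusted p = 0.0354) passed without EZH2 siRNA no.2 replicate 1, the latter also with every probe set (0.18, adjusted p = 0.0144), and fibroblast genes without TSA replicate 1 (−0.56, adjusted p = 0.0454).

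Among single genes, EZH2 itself differed (log2 1.80, SE 0.45, limma adjusted p = 0.00625). DYNC1LI2 (1.66, SE 0.38), TMEM50A (1.90, SE 0.54), HIPK1 (1.22, SE 0.35) and GRP (1.04, SE 0.32) stood higher with TSA than with the siRNA. ASPH (−1.40, SE 0.37), IL7R (−2.34, SE 0.63), OPRK1 (−2.42, SE 0.65), SAYSD1 (−1.63, SE 0.46) and OCEL1 (−1.51, SE 0.43) stood lower. TMEM50A, HIPK1 and OPRK1 gave −1.69, −0.65 and 1.26 with EZH2 siRNA no.2, but −0.05, 0.40 and −0.09 with the unnumbered EZH2 siRNA. The other genes named so far in this paragraph had the same sign with both siRNAs. Over the other settings IL7R ran from −3.26 to −1.33, OPRK1 from −3.35 to −1.36 and SAYSD1 from −2.05 to −1.02. Other probe sets differed less, reading −0.37 with the siRNA and −0.19 with TSA for DYNC1LI2, −0.49 and −0.18 for HIPK1, and 0.45 and −0.14 for ASPH. EMP1 (−0.58, SE 0.59), GAP43 (0.42, SE 0.44) and NGFR (0.12, SE 0.58) differed by less than their standard error. Over all genes 0 passed limma (lowest adjusted p = 0.999, with 0.997 to 1.00 over the other settings). At the unadjusted level 163 had an unadjusted p under 0.05, fewer than the 455 that chance alone gives. Of these 51 were higher and 112 lower (63 and 114 after quantile normalization, 71 and 85 with each array scaled to the same median). The other settings gave 113 to 315. This count was 375 without TSA replicate 2, 354 without control siRNA replicate 1 and 252 without EZH2 siRNA no.2 replicate 1.

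DMSO was set against the control siRNA as a comparison of the control groups, which differ in solvent, transfection and time. Metallothioneins stood apart, with MT1E at −2.25 (SE 0.57), MT1X at −2.04 (SE 0.49) and MT2A at 1884 ± 58.8 in DMSO against 5688 ± 3540 with the control siRNA (log2 −1.43, SE 0.39). They belong to the list of genes known to answer deacetylase inhibitors, of which 6 passed limma adjusted over the list alone and 10 of 19 were negative, with TXNIP at 1.39 (SE 0.56). Its mean was −0.44 ± 0.24 (camera adjusted p = 0.00279, and adjusted p = 0.373 with an estimated correlation). This call was lost with every probe set (−0.28), without DMSO replicate 2 (−0.39, adjusted p = 0.184) and without control siRNA replicate 1 (−0.16, adjusted p = 0.744). The mean was −0.72 without control siRNA replicate 2. Cholesterol synthesis genes were higher in DMSO, with 10 of 10 positive and a mean of 0.50 ± 0.11 (adjusted p = 0.000599, and adjusted p = 0.373 with an estimated correlation). FDPS (1.02, adjusted p = 0.0264), INSIG1 (1.00, adjusted p = 0.0246) and HMGCS1 (0.87, adjusted p = 0.0264) rose in limma adjusted over the list alone.

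Stress genes were also higher in DMSO, with 9 of 12 positive and a mean of 0.36 ± 0.15 (adjusted p = 0.0492, and adjusted p = 0.918 with an estimated correlation). ASNS (1.33, SE 0.36) and TRIB3 (1.31, SE 0.37) rose in limma adjusted over the list alone (adjusted p = 0.0255 each). This call was lost without control siRNA replicate 2 (0.13, adjusted p = 0.892), without DMSO replicate 2 (0.28, adjusted p = 0.407) and without DMSO replicate 1 (0.44, adjusted p = 0.0503). The mean was 0.58 without control siRNA replicate 1. It passed in only 5 of 13 other settings and was lost with a batch block (adjusted p = 0.114), with no filter, with the pseudocount of the 5th percentile, with each array scaled to the same median (0.26), without the eBayes trend and with every probe set. Of all genes 0 passed (lowest adjusted p = 1.00, with 0.544 to 1.00 over the other settings). At the unadjusted level 418 had an unadjusted limma p under 0.05, where chance alone gives 455. Of these 310 were higher and 108 lower (276 and 130 after quantile normalization, 201 and 176 with each array scaled to the same median). The count was 320 to 668 over the other settings and 224 without DMSO replicate 1.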

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

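Setting TSA against the control siRNA for the cholesterol list was decided only after its result was seen.

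The differences between the TSA effect and the EZH2 siRNA no.2 effect of −0.52 for cholesterol synthesis genes and −0.63 for stress genes stood out because the difference between the effects was itself tested. In TSA against the control siRNA the cholesterol mean was −0.0475 ± 0.12 and the stress mean 0.0169 ± 0.13, while DMSO against the control siRNA gave 0.50 ± 0.11 and 0.36 ± 0.15, so the DMSO arrays may carry the cholesterol difference. They may carry only part of the stress difference, since 0.29 of it is the higher mean with EZH2 siRNA no.2, a comparison without DMSO. For stress genes DMSO (0.36) thus did not stand apart from EZH2 siRNA no.2 (0.29), as both lay above the control siRNA. DMSO against the control siRNA gave 0.13 without control siRNA replicate 2, so which arrays carry the stress difference cannot be told. A trend of the fold changes with mean signal and genomic span was excluded for the cholesterol list, whose mean lay at percentile 0 of 10000 matched random lists, with a median of −0.06 and 95% of them between −0.24 and 0.12. The siRNA and DMSO groups differ in transfection and time as well, so a true effect of TSA or of the solvent on sterol and amino acid response genes stays open.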

How the results depend on the processing

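These values come from 9 arrays of 1 cell line, with 2 arrays per group and 1 for the unnumbered EZH2 siRNA, and the cause of each change was not tested. With all arrays kept, the settings held the direction of 863 of 863 fold changes of named genes. Most of these genes were chosen for non-overlapping groups, and some settings leave the fold change unchanged, so this count is a weak test. Sizes moved more, from 0.96 to 2.52 for IL7R with EZH2 siRNA no.2 and from 0.66 to 2.15 for HTR1E with TSA. With an array left out, 361 of 368 fold changes kept their direction and 7 reversed. With all arrays kept, 65 of 65 counts of genes past the threshold stayed at 0.

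With an estimated correlation 0 lists were called in every comparison. For EZH2 siRNA no.2 the count of called lists was 2, with 1 after quantile normalization, 3 with each array scaled to the same median, 3 after the later adjustment for signal and span, and 0 to 4 with an array left out. For TSA it was 3, with 4 without the filter, 4 with every probe set, 2 after the adjustment, and 1 to 3 with an array left out. For the unnumbered EZH2 siRNA it was 0, with 0 to 2. For the mean of both siRNAs it was 1, with 0 without the filter, 2 with the 50th percentile filter, 3 with every probe set, 2 after the later adjustment for signal and span, and 0 to 3 with an array left out. For the difference of effects it was 2, with 3 for every probe set and 1 to 5 with an array left out, and for DMSO against the control siRNA 3, with 1 for every probe set and 1 to 4 with an array left out.

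EZH2 with the unnumbered siRNA gave −0.91 with the batch block added later (adjusted p = 0.0379, with 0.0379 to 0.162 over all settings). The correlation of EZH2 siRNA no.2 with TSA was 0.329 with the 50th percentile filter and 0.111 to 0.284 with an array left out, and that of both siRNAs 0.416 to 0.744. With an array left out, the difference of effects ran from −1.17 to 0.0183 for EMP1, from −0.0271 to 0.87 for GAP43 and from −0.34 to 0.57 for NGFR, with −0.30 and −0.26 between them. DMSO against the control siRNA ran from −0.0561 to 1.13 for EMP1 and from −0.28 to 0.62 for GAP43.

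Deviations of same-numbered arrays correlated at 0.0529 to 0.377, and the hybridisation controls and the first principal component split the arrays by number, but with 2 numbers and no label of a shared culture or day the pairing stays unknown. With a replicate block 0 genes passed, 807 genes with EZH2 siRNA no.2 and 414 with TSA had an unadjusted p under 0.05 (315 for the difference of effects and 668 for DMSO against the control siRNA). Lists called stayed at 2, 3 and 2 but were 2 for DMSO against the control siRNA, where the stress list was lost (adjusted p = 0.114). With the replicate block EZH2 was −1.48 with EZH2 siRNA no.2 (adjusted p = 0.000850) and 0.31 with TSA, the correlation was 0.255, and no other call changed.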

Other observations

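The gene families, the setting of DMSO against the control siRNA for the fusion-repressed list, the crossed splits of the arrays and the adjustment of the correlation for signal and span were chosen only after the results were seen.

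Subunits of respiratory chain complex I were lower with EZH2 siRNA no.2 and with TSA. With EZH2 siRNA no.2, 29 of 31 NDUF genes were negative (mean −0.43, camera adjusted p = 3.62e-10, and adjusted p = 0.641 with an estimated correlation). Among them were NDUFA1 (−1.53, SE 0.38), NDUFB11, at 1499.7 ± 397 against 3331 ± 833 (n = 2 each, log2 −1.14, SE 0.34), and NDUFB8 (−0.91, SE 0.25, with −0.31 and 0.15 on its other probe sets). With TSA 29 of 31 were negative too (mean −0.40, adjusted p = 2.09e-10, and adjusted p = 0.720 with an estimated correlation). NDUFB11 stood at −1.02 (SE 0.34), NDUFB3 at −0.81 (SE 0.32) and NDUFB5 at −0.61 (SE 0.24). The means of replicate 1 and replicate 2 were −0.62 and −0.24 with EZH2 siRNA no.2 and −0.74 and −0.06 with TSA. On the single array of the unnumbered EZH2 siRNA, which had low hybridisation controls like the replicate 1 arrays, 26 of 31 were negative (mean −0.44, adjusted p = 3.7e-07, 0.000216 with a batch block and 0.963 with an estimated correlation). ATP synthase genes followed, with 16 of 17 negative for EZH2 siRNA no.2 (mean −0.37, adjusted p = 9.86e-06) and for TSA (mean −0.29, adjusted p = 0.000123). So did cytochrome c oxidase genes (means −0.19 and −0.28, adjusted p = 0.00583 and 0.00034), mitochondrial ribosome genes (−0.15 and −0.22, adjusted p = 0.000537 and 9.31e-06) and large ribosomal subunit genes (−0.26 and −0.27, adjusted p = 3.13e-06 and 2.53e-06). None of these families passed with an estimated correlation (adjusted p = 0.641 to 0.716 with the siRNA and 0.720 with TSA). They were lower mainly in replicate 1, with replicate 2 means of 0.00 and 0.01 for cytochrome c oxidase, 0.03 and 0.06 for mitochondrial ribosome, 0.08 and 0.09 for large ribosomal subunit and −0.10 and 0.06 for ATP synthase genes. After the adjustment for mean signal and genomic span the large ribosomal subunit means were −0.13 and −0.09, and matched random lists had medians of −0.12 and −0.17 before it.

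Proteasome core genes were lower in TSA, with 15 of 16 negative (mean −0.39, adjusted p = 3.42e-06, and adjusted p = 0.720 with an estimated correlation), but by replicate number the means were −0.79 and 0.00. They stood at −0.11 with EZH2 siRNA no.2 (adjusted p = 0.0941), and the difference of −0.28 did not pass (adjusted p = 0.312). Zinc finger genes had 137 of 183 positive in TSA (mean 0.19, adjusted p = 0.000184, and adjusted p = 0.720 with an estimated correlation) and 127 with EZH2 siRNA no.2 (mean 0.17, adjusted p = 0.0648). Collagen genes had 17 of 22 positive with EZH2 siRNA no.2 (mean 0.37, adjusted p = 0.00871, and adjusted p = 0.641 with an estimated correlation) and a mean of 0.16 in TSA (adjusted p = 0.130). Metallothioneins had 7 of 7 negative with EZH2 siRNA no.2 (mean −0.54, adjusted p = 0.00583, and adjusted p = 0.641 with an estimated correlation), but 5 of 7 positive with the unnumbered siRNA (mean 0.11, adjusted p = 0.965), and a mean of −0.01 in TSA (adjusted p = 0.858). In DMSO against the control siRNA 7 of 7 were negative (mean −1.81, adjusted p = 5.95e-15, and adjusted p = 0.664 with an estimated correlation). By replicate number the metallothionein means were −0.998 and −0.07 with EZH2 siRNA no.2 and −2.76 and −0.85 in DMSO. By replicate number collagens gave 0.17 and 0.57 with EZH2 siRNA no.2 and zinc finger genes 0.25 and 0.12 in TSA. Histone genes did not pass with either treatment (means −0.02 and 0.12, adjusted p = 0.688 and 0.426).

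For the higher signals of fusion-repressed genes with EZH2 siRNA no.2 (mean 0.53), 3 explanations besides the biology were examined, and others are possible. DMSO against the control siRNA gave −0.0220 ± 0.12 (SEM over genes), so the control siRNA arrays did not stand low for this list against DMSO. These groups also differ in solvent, transfection and time, so control siRNA arrays that stand apart could not be excluded. A trend with mean signal and genomic span was excluded, since the mean lay at percentile 100 of the matched random lists, 95% of which lay between −0.11 and 0.28. A difference within one replicate number could not be excluded, as the smaller of the replicate means was 0.293 of the larger. That these genes are under EZH2 control in cells with the fusion stays open and was not tested here.

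The correlation between the EZH2 siRNA no.2 and TSA effects may come from arrays that differ for reasons other than their group. Splitting both sides by replicate number gave 0.333, above the 0.255 of the groups, so same-numbered arrays shared differences across the comparisons. Crossed splits of the arrays still correlated at 0.242, and at 0.0287 to 0.171 where only one side was crossed, but they cancel only effects of equal size in both replicates, and EZH2 gave −0.95 and −2.02, so this stays open. The correlation was 0.215 after the adjustment for mean signal and genomic span, so such a trend alone was excluded. For complex I genes the same trend was excluded, at percentile 0 of the matched lists in both comparisons, while the smaller replicate mean in TSA was 0.0874 of the larger, which fits a difference in one replicate number there but stays open for EZH2 siRNA no.2 with −0.62 and −0.24. The 28S ribosomal RNA signal was lower than in the controls in replicate 1, as complex I was, and higher in replicate 2, with log2 values of 6.94 in replicate 1 and 8.43 in replicate 2 of TSA, 7.14 and 8.57 for EZH2 siRNA no.2, 7.51 and 7.94 for DMSO, 7.64 in both for the control siRNA, and 6.76 for the unnumbered siRNA, and a shared target of EZH2 and the deacetylases stays open.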
